A study of Mus musculus with 10 samples.

How the data were processed

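The values were gene-level RNA-seq levels from 7 libraries of C57BL/6J mouse embryonic stem cells, prepared as stranded total RNA after ribosomal RNA depletion. The labels name 1 library of the wild-type line MK6 and 3 converted lines with 2 libraries each: conv-dSVA_F, conv-dSVA_D and conv-dSVA_F&D. Each converted line carries an engineered Taf1 allele with a human-derived part, has been treated with Cre, and lacks the SVA retrotransposon insertion or insertions given in its name. The cells were grown on gelatin in medium with serum, LIF, the GSK3 inhibitor CHIR99021 and the MEK inhibitor PD0325901. The series holds 10 samples. The pre-conversion XDP stem cell library and the 2 striatal libraries of week 3 were not analysed here.

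The deposited signal was, per the file and its values, a table of normalized counts: gene counts divided by the authors by 1 size factor per library and rounded to 2 decimals. The submitters' processing notes name Trimmomatic 0.36, STAR 2.7.3, Picard 2.18.20, featureCounts 1.6.3, deepTools 3.1.0, DESeq2 and the build mm10. Roles, strand setting and annotation were not given in the sources used here. Whole reads were recovered from the smallest step between values in each column. In each of the 7 libraries 100% of the positive values lay within 0.1 read of a whole number. The size factors differed from DESeq2's median of ratios by at most 1.03e-08 of their value.

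Recovered reads assigned to genes were 22385569 and 26562418 in conv-dSVA_D replicates 1 and 2, 24875359 and 21360424 in conv-dSVA_F, 23541885 and 16588467 in conv-dSVA_F&D, and 21274792 in the wild type. A gene at 0 in 1 library could have had up to 3 reads, which corresponds to 2.45 to 4.18 normalized counts depending on the library. Such limits cover counting error only. The table held 54456 genes, of which 50716 (93.1%) matched a gene name in the GENCODE mouse release M21 annotation of GRCm38. Positions, biotypes and chromosome analyses rest on these matches.

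The test was limma 3.58.1 with a variance trend (lmFit and eBayes in R 4.3.3) on log2 of the normalized count plus 1. It covered 15240 genes with a mean of at least 10 over the libraries. The model had 1 mean for each of the 4 groups and no other term, since the labels name no batch. The residual degrees of freedom were 3 and the prior degrees of freedom 6.80. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Comparisons were conv-dSVA_F&D with conv-dSVA_D, conv-dSVA_F&D with conv-dSVA_F, conv-dSVA_F with conv-dSVA_D, any difference among the 3 converted groups (moderated F test), and the mean of the converted groups with the wild type. The single wild-type library was assumed to vary like the converted groups. Differences are log2 of the first group over the other, ± the standard error, and the added count of 1 understates differences of genes with few reads. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical in part. Pearson r of log2 levels over tested genes was 0.979 between conv-dSVA_D replicates, 0.974 in conv-dSVA_F and 0.959 in conv-dSVA_F&D. For conv-dSVA_F&D replicate 1, r was higher with the wild type (0.969) and conv-dSVA_D replicate 2 (0.969). Its chi-square per degree of freedom of reads was lowest with its own replicate 2 (37.7, against 46.2 with conv-dSVA_F replicate 2). The labels give 1 line name per genotype and no clone, so genotype and line or clone cannot be told apart.

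Marker and pathway lists (32) were tested with camera in limma at a preset inter-gene correlation of 0.01. The 31 lists with at least 5 genes tested were adjusted together within each comparison. The list of other striatal neuron markers had fewer and was not tested. An estimated correlation and the self-contained fry test were run beside it. No list call held with an estimated correlation in any comparison, and fry kept 3 calls in the first comparison and 0 in the others, as given beside the lists. The lists, comparisons, tests, threshold, most alternative settings and the rule for naming genes were fixed before the data were examined. The rule names Taf1 in every comparison and other TFIID subunits and X-linked genes near Taf1 that passed. It further names up to 10 genes per direction with the largest difference among genes past the threshold with a mean of at least 100 and no overlap between the libraries of both sides, leaving out predicted-gene, clone and pseudogene names. From each called list it names up to 4 members with the smallest p.

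Chromosome medians were added after the data were seen. They are the median log2 difference from the wild-type library over 10664 protein-coding genes with a mean of at least 50, less the median over all of these genes. They were compared with 10000 random gene sets of the same size. Chromosomes were split into 6 parts with equal gene numbers. Enrichment of called genes by chromosome used Fisher's exact test over all 15240 tested genes, adjusted over 84 tests. Of these genes 14776 had a position, and the rest were counted as lying off the chromosome in question.

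In simulated data 100 genes were changed 2-fold and 100 others 4-fold, up or down. The 2-fold change was recovered for 62.0%, 57.0%, 51.0% and 43.0% of its genes in the 4 pairwise comparisons in the order above. The 4-fold change was recovered for 94.0%, 96.0%, 93.0% and 83.0% of its genes. False calls made up 4.29%, 6.71%, 8.28% and 6.67% of the calls, and 0 of 20 unchanged lists were called. Each gene had the same simulated dispersion in every library, the wild type included, and no chromosome was shifted. The shares of false calls hold under these conditions only. Genes were simulated independently of each other, so the result for lists does not cover lists whose genes vary together. The estimated correlation within the tested lists reached 0.77. A simulated chromosome shift of 0.58 came back as 0.56, with the other 19 chromosomes within 0.06 of 0.

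Alternatives were another added count (0.5 or 5), no low-value filter, a mean of at least 50, quantile normalization, upper-quartile scaling, edgeR 4.0.16 with TMM scaling, DESeq2 1.42.0, only the libraries of both sides, no variance trend, and each converted library left out. Added after the data were seen were leaving out chromosomes 6, 8, 18 and Y, setting chromosome medians equal, and protein-coding genes only. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.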

Results

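Taf1, which encodes the largest subunit of the general transcription factor TFIID, was measured first in every library because it is the edited gene. Its level was 2898 normalized counts in the wild-type library, 501 and 589 in conv-dSVA_F replicates 1 and 2, 362 and 418 in conv-dSVA_D, and 1116 and 1088 in conv-dSVA_F&D. Group means were 545 ± 62.1 (SD, n = 2) in conv-dSVA_F, 390.0 ± 39.6 (SD, n = 2) in conv-dSVA_D and 1102 ± 19.9 (SD, n = 2) in conv-dSVA_F&D. These are 18.8%, 13.5% and 38% of the wild-type value. Taf1 was higher in conv-dSVA_F&D than in conv-dSVA_D (log2 difference 1.5 ± 0.15, adjusted p = 0.00456) and than in conv-dSVA_F (1.02 ± 0.15, adjusted p = 0.0139). The difference of 0.48 ± 0.15 between conv-dSVA_F and conv-dSVA_D did not pass (adjusted p = 0.155). The mean of the converted groups was lower than the wild type by a log2 difference of -2.23 ± 0.17 (adjusted p = 0.00177), with lower values in 6 of 6 converted libraries.

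Taf1 (ENSMUSG00000031314) lies on the plus strand of chromosome X at 101532734 to 101601789 (GRCm38), and its principal annotated transcript with the most exons has 39. Intron 24, which the labels give as the loxP site, spans 101562980 to 101563527. Exons 1 to 24 hold 65.7% of the 5954 exon bases. Whether reads from the human-derived part of the allele were counted as Taf1 is not given in the sources used here, so the comparison with the wild type may not measure the same exons. Among the converted lines, the call against conv-dSVA_D was lost without conv-dSVA_D replicate 1 (adjusted p = 0.0597, log2 difference 1.4 to 1.6 over all left-out libraries). The call against conv-dSVA_F was lost without conv-dSVA_F replicate 1 (adjusted p = 0.147, range 0.90 to 1.14). No low-value filter gave adjusted p = 0.148 and 0.15 in these comparisons, no variance trend gave 0.142 and 0.191, and both left the differences at 1.5 and 1.02. For the comparison with the wild type, no variance trend gave 0.176 and fitting each side as 1 group gave 0.329.

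**Figure D1:**
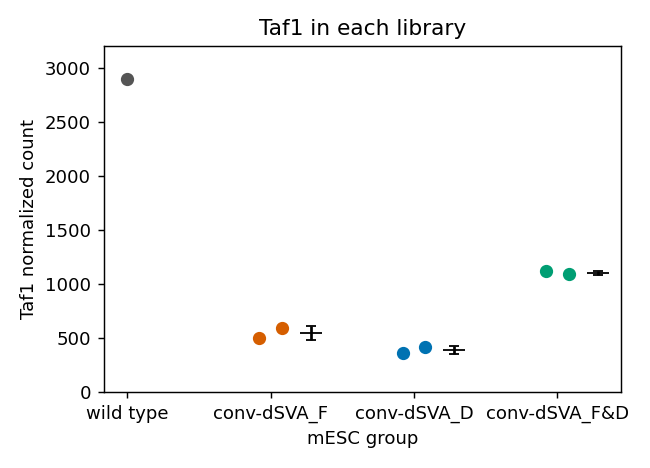
Taf1 level in normalized counts (vertical axis) for each library, with group means and SD of the 3 converted groups. The 6 converted libraries sit between 362 and 1116, below the wild-type value of 2898.

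Median levels of whole chromosomes differed between libraries. Against the wild type, the median log2 difference of chromosome 8 was 0.63 and 0.44 in conv-dSVA_F replicates 1 and 2, 0.07 and 0.24 in conv-dSVA_D, and 0.00 and -0.01 in conv-dSVA_F&D. For chromosome 6 these values were 0.41 and 0.36, 0.15 and 0.14, and 0.00 and -0.01. Chromosome 18 stood at 0.51 in conv-dSVA_F&D replicate 2 and between -0.10 and -0.03 in the 5 other converted libraries. The 16 other autosomes lay between -0.14 and 0.07. Chromosome Y, with 6 genes, stood at -1.04 and -1.41 in conv-dSVA_D replicates 1 and 2, -0.29 and 0.34 in conv-dSVA_F, and 0.93 and 0.78 in conv-dSVA_F&D. Of 7 tested Y genes 4 were called between conv-dSVA_F&D and conv-dSVA_D (Fisher's exact test, adjusted p = 0.000449). None of 10000 random gene sets of the same size, drawn from the 16 other autosomes, reached the chromosome 6 and 8 medians of conv-dSVA_F. The same held for chromosome 6 in conv-dSVA_D replicates 1 and 2, chromosome 8 in conv-dSVA_D replicate 2 and chromosome 18 in conv-dSVA_F&D replicate 2. Only chromosomes 6, 8 and 18 were compared, after their medians were seen, and they were left out of the pool. The random sets are therefore no separate test of these shifts. In conv-dSVA_D the rise on chromosome 6 was uneven. The first 2 of 6 parts had medians of -0.23 to -0.15, and the last 2, from 113728062 to 149563329, had medians of 0.47 to 0.54. Genes on chromosomes 6 and 8 therefore carried part of the differences between groups. These chromosomes hold 10% of the tested genes and held 78.6% of the genes lower in conv-dSVA_F&D than in conv-dSVA_F.

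**Figure D2:**
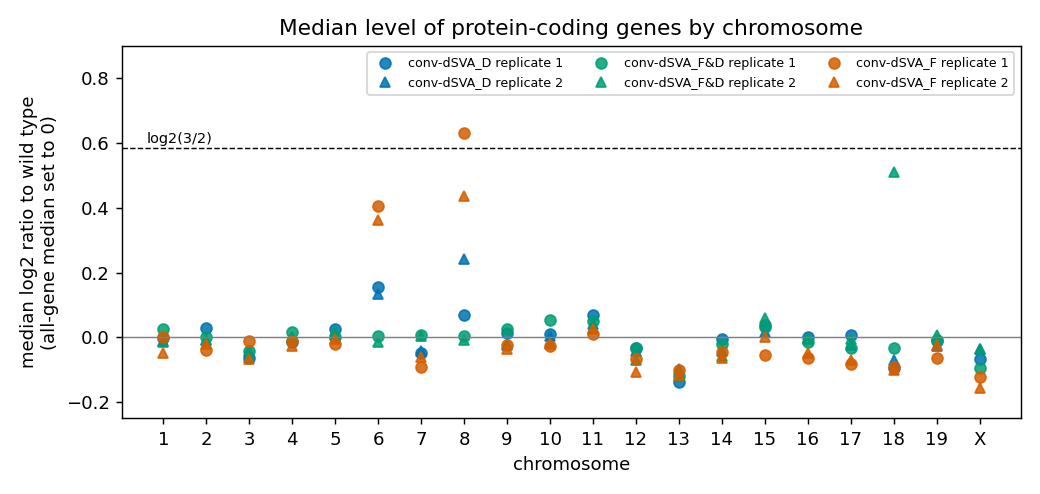
Median log2 difference from the wild-type library (vertical axis) for each chromosome in each converted library. Chromosomes 6 and 8 are raised in conv-dSVA_F (0.36 to 0.63) and chromosome 18 in conv-dSVA_F&D replicate 2 (0.51).

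**Figure D3:**
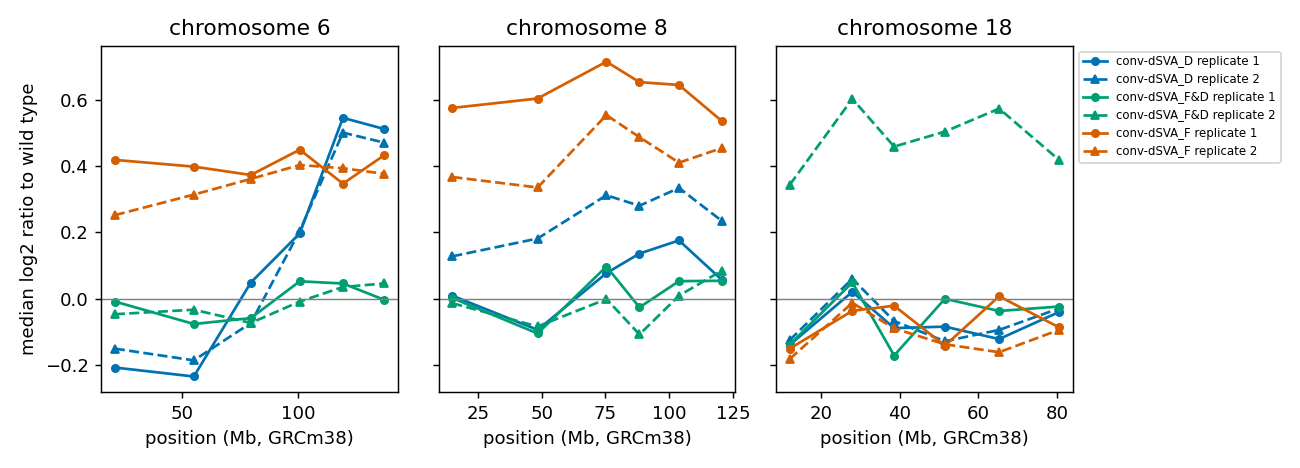
Median log2 difference from the wild-type library along 6 parts of chromosomes 6, 8 and 18 with equal gene numbers, for each converted library. The last 2 parts of chromosome 6 reach 0.47 to 0.54 in conv-dSVA_D.

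Between conv-dSVA_F&D and conv-dSVA_D, which differ in the labels by the SVA_F deletion, the gene with the largest difference was H19, an imprinted long noncoding RNA. H19 rose from 12.1 ± 3.25 normalized counts in conv-dSVA_D (SD, n = 2) to 973 ± 649 in conv-dSVA_F&D (SD, n = 2), a log2 difference of 6.06 ± 0.60 (adjusted p = 0.00407). Its level was 350 in the wild-type library and 2100 and 554 in conv-dSVA_F replicates 1 and 2. For H19 the conv-dSVA_D libraries therefore stood apart from all others, the wild type included. Of 14 genes of the 2-cell-like state, a rare state of embryonic stem cells with transcripts of the early embryo, 6 rose, among them Tmem92 (10.5 ± 1.29 to 138 ± 51.1) and Zscan4a (12.6 ± 4.18 to 146 ± 74.5; the list's adjusted p = 0.397 with an estimated correlation). The Y-linked ubiquitin-activating enzyme gene Uba1y rose from 164 ± 21.9 to 1138 ± 126. The largest fall was in the testis-expressed X-linked gene Tex13b, from 558 ± 1.46 to 72.6 ± 47.5 (-3.09 ± 0.42, adjusted p = 0.0110). Tex13b was also lower in the wild type and in both conv-dSVA_F libraries than in conv-dSVA_D, so conv-dSVA_D stood apart here too.

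None of the 14 2-cell-like genes fell and 8 did not pass (10 rose when adjusted over the list alone). The list had a median of 2.28 (camera adjusted p = 1.29e-08; adjusted p = 0.397 with an estimated correlation). Tmem92 (3.55 ± 0.42, adjusted p = 0.00874), Zscan4a (3.38), Zscan4c (2.56) and Zscan4d (2.42) led it. The Zscan4 genes are near-identical copies, so reads may be shared among them. Of 11 trophoblast genes, 3 rose and 4 did when adjusted over the list alone (median 1.49, camera adjusted p = 9.01e-05; adjusted p = 0.569 with an estimated correlation). These were the simple-epithelial keratins Krt8 (80.1 ± 18.3 to 414 ± 133, 2.34) and Krt18 (2.08) and the trophoblast transcription factor Ascl2 (1.30), while Krt7 stood at 2.38 ± 0.63 (adjusted p = 0.0741). Of 5 Y-linked genes, Ddx3y (1.24), Uty (2.45) and Zfy1 (2.94) rose, and 4 did when adjusted over the list alone (median 1.84, camera adjusted p = 2.03e-06; adjusted p = 0.397 with an estimated correlation, 0.0486 with fry). Kdm5d stood at 1.84 ± 0.48 (adjusted p = 0.0698).

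Of 18 TFIID subunit genes, Taf12 (-0.99 ± 0.16), Taf5 (-0.82 ± 0.15) and Taf6 (-0.72 ± 0.14) fell and Taf1 rose, with 1 higher and 4 lower when adjusted over the list alone (median -0.24, camera adjusted p = 0.0284; adjusted p = 0.397 with an estimated correlation). Of 21 X-linked genes near Taf1, Taf1 and the transcriptional coactivator gene Cited1 (1.28 ± 0.27, adjusted p = 0.0408) rose, and 4 were higher and 1 lower when adjusted over the list alone. Tex11 (0.86, adjusted p = 0.0885) and Gjb1 (2.72, adjusted p = 0.0906) did not pass. This list had a median of 0.37 (camera adjusted p = 0.00432; adjusted p = 0.397 with an estimated correlation, 0.0486 with fry). Of 17 dystonia-related genes only Taf1 passed, over all genes and adjusted over the list alone (median 0.22, camera adjusted p = 0.0214; adjusted p = 0.397 with an estimated correlation, 0.0486 with fry). Slc2a1 (0.40, adjusted p = 0.15) and Gnal (0.91, adjusted p = 0.159) did not pass. The TFIID, X-linked and dystonia-related lists all include Taf1, and none was tested without it.

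Camera called 7 further lists. Of 14 WNT target genes 3 rose (4 adjusted over the list alone): the WNT deacylase Notum (1.23), the receptor gene Tnfrsf19 (1.14) and Ascl2, with Lef1 at 1.99 (adjusted p = 0.0698; list median 0.38, camera adjusted p = 0.0345; adjusted p = 0.604 with an estimated correlation). Of 8 glial and vascular genes the myelin gene Mbp (2.29) and the lineage factor Olig2 (1.08) rose (3 adjusted over the list alone), with Pecam1 at 0.52 and Olig1 at 0.54 not past (median 0.32, camera adjusted p = 0.0284; adjusted p = 0.397 with an estimated correlation). Of 24 germline genes the meiotic chromosome-axis gene Hormad1 rose (0.93), and 5 did when adjusted over the list alone (median 0.48, camera adjusted p = 0.0345; adjusted p = 0.619 with an estimated correlation). Ddx4 (1.06), Fkbp6 (1.05) and Rhox5 (1.44) did not pass. Of 21 glycolysis and hypoxia genes the stress-response gene Ndrg1 rose (1.17), with 4 higher and 1 lower when adjusted over the list alone (median 0.28, camera adjusted p = 0.0284; adjusted p = 0.754 with an estimated correlation). Egln3 (1.39), Slc2a3 (-0.52) and P4ha1 (0.65) did not pass.

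Of 20 genes of the G2 and M phases the survivin gene Birc5 fell (-0.48), and 4 fell when adjusted over the list alone (median -0.10, camera adjusted p = 0.0345; adjusted p = 0.569 with an estimated correlation), with Ccnb2 at -0.42, Cenpf at -0.45 and Ccna2 at -0.35. None of 13 primitive endoderm genes passed over all genes with limma (7 at unadjusted p under 0.05, 0 with edgeR, 5 with DESeq2), and 5 were higher and 1 lower when adjusted over the list alone (median 0.72, camera adjusted p = 0.0284; adjusted p = 0.540 with an estimated correlation). The basement membrane genes Lama1 (-0.97), Lamb1 (0.43), Sparc (0.42) and Col4a1 (0.90) had the smallest p. None of 40 ribosomal protein genes passed with limma (15 at unadjusted p under 0.05, 2 with edgeR, 6 with DESeq2), and 3 were higher when adjusted over the list alone (median 0.22, camera adjusted p = 1.88e-07; adjusted p = 0.569 with an estimated correlation). Rplp1 stood at 0.63 (adjusted p = 0.0515), Rplp0 at 0.48, Rps16 at 0.49 and Rps13 at 0.43. Ribosomal protein genes have many processed pseudogenes that may share their reads. Of the 31 lists tested 13 were called, and 7 without conv-dSVA_F&D replicate 1.

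Outside these lists, Dnai2 (a dynein chain of cilia, 3.27), Col5a3 (a collagen chain, 2.59), Ckmt1 (a mitochondrial creatine kinase, 2.52), Ccdc136 (2.46) and Sema5a (a guidance cue, 2.46) rose. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, fell from 1307 ± 713 to 271 ± 173 (-2.32 ± 0.44, adjusted p = 0.0271). Caprin2 (-1.87) and Iffo1 (-1.44), both on chromosome 6, Junb (an AP-1 factor on chromosome 8, -1.51), Adam23 (-1.65), Acot13 (-1.63), Tor3a (-1.62), Tro (-1.49) and the zinc transporter gene Slc39a14 (-1.42) also fell. Of 177 small noncoding RNAs tested, 10 rose and 0 fell (median 0.34). Over all annotated small noncoding RNAs, tested or not but without the abundant 7SK and Rmrp RNAs, shares of reads were also taken. The share was 1.22% in conv-dSVA_F&D replicate 2 and 0.830% in its replicate 1, against 0.692% and 0.778% in conv-dSVA_D replicates 1 and 2 (Wilson 95% intervals 1.211 to 1.222, 0.827 to 0.834, 0.689 to 0.695 and 0.775 to 0.782). Without conv-dSVA_F&D replicate 2, 4 rose (median 0.17), and without its replicate 1, 20 rose and 4 fell. Without conv-dSVA_D replicate 1 none passed with limma (20 at unadjusted p under 0.05, other tools not run), and without its replicate 2, 1 rose.

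In all, 482 of 15240 genes passed with limma, 298 higher and 184 lower in conv-dSVA_F&D. In each of the 482 the libraries of the groups did not overlap. With 2 libraries per group a call nearly requires this, here and in the comparisons below, so it adds no support. Of the 482 genes, 231 differed at least 2-fold (181 higher, 50 lower). Chromosomes 6 and 8 held 83 of the 184 lower genes (45.1%). Chromosome 6 held 70 called genes, 63 of them lower (Fisher's exact test, adjusted p = 1.27e-15). Without chromosomes 6, 8, 18 and Y, 350 genes passed (253 higher, 97 lower). The count was 1041 with DESeq2, 463 with edgeR, 246 with only the libraries of both sides, 0 with no variance trend (2452 at unadjusted p under 0.05) and 0 with no low-value filter (3823). It was 0 with limma without conv-dSVA_D replicate 1 (1866 at unadjusted p under 0.05, other tools not run), 40 (38 higher, 2 lower) without conv-dSVA_D replicate 2, 259 and 241 without conv-dSVA_F replicates 1 and 2, 769 (372 higher, 397 lower) without conv-dSVA_F&D replicate 1 and 300 without its replicate 2.

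Between conv-dSVA_F&D and conv-dSVA_F, which differ in the labels by the SVA_D deletion, 9 of 21 glycolysis and hypoxia genes rose (the list's adjusted p = 0.733 with an estimated correlation). They included the glucose transporter gene Slc2a1 (4740 ± 942 normalized counts in conv-dSVA_F to 7984 ± 541 in conv-dSVA_F&D, SD, n = 2) and the glycolytic enzyme gene Eno1 (14823 ± 4904 to 29201 ± 1577). The WNT effector gene Lef1 rose from 78.9 ± 40.6 to 648 ± 396 (2.97 ± 0.51, adjusted p = 0.0201). The imprinted gene Mest, on chromosome 6, fell from 3493 ± 40.4 to 792 ± 174 (-2.16 ± 0.20, adjusted p = 0.00425). Pramel6, a PRAME-family gene expressed in the early embryo, fell from 643 ± 425 to 49.0 ± 12.2 (-3.53 ± 0.47, adjusted p = 0.0114).

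None of the 21 glycolysis and hypoxia genes fell and 12 did not pass (16 rose when adjusted over the list alone), with a median of 0.79 (camera adjusted p = 2.21e-09; adjusted p = 0.733 with an estimated correlation). Ndrg1 (1.63 ± 0.27, adjusted p = 0.0183), Slc2a1 (0.76), Eno1 (1.02) and Egln3, an oxygen-sensing hydroxylase gene (1.78), had the smallest p. Of 22 imprinted genes 1 rose and 3 fell (1 and 6 adjusted over the list alone; median -0.39, camera adjusted p = 0.0199; adjusted p = 0.733 with an estimated correlation). The growth-factor receptor adaptor gene Grb10 rose (1.63), and Mest, Nnat (-1.84) and Sgce (-3.12) fell, with Mest and Sgce on chromosome 6. Of 14 WNT targets Lef1 and Notum (1.09) rose (3 adjusted over the list alone; median 0.38, camera adjusted p = 0.0309; adjusted p = 0.733 with an estimated correlation), and Tnfrsf19 (0.85) and Dkk1 (-1.5) did not pass. Of 19 naive pluripotency genes Klf2 (0.69) and Tcl1 (0.95) rose, the same number as when adjusted over the list alone (median 0.24, camera adjusted p = 0.0309; adjusted p = 0.754 with an estimated correlation). Tbx3 stood at 0.48 (adjusted p = 0.128). Zfp42, on chromosome 8, stood at -0.41 (adjusted p = 0.138) and at 0.13 with chromosome medians set equal.

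Of 5 Y-linked genes Zfy1 (3.08) and Ddx3y (0.69) rose, 2 also when adjusted over the list alone (median 0.69, camera adjusted p = 0.0240; adjusted p = 0.733 with an estimated correlation), with Uty at 0.59 and Kdm5d at 0.80. None of 40 ribosomal protein genes passed with limma, over all genes or adjusted over the list alone (3 at unadjusted p under 0.05, 0 with edgeR, 0 with DESeq2; median 0.15, camera adjusted p = 0.00293; adjusted p = 0.916 with an estimated correlation). Rpl4 (0.35) and Rpl6 (0.24) were higher without passing, and Rpl13, on chromosome 8, stood at -0.39 and at 0.15 with chromosome medians set equal. Among TFIID subunits Taf1 rose and Taf12 fell (-0.84 ± 0.16, adjusted p = 0.0242), and among X-linked genes near Taf1 only Taf1 passed. Of the 31 lists tested 6 were called, 2 without conv-dSVA_F replicate 1 and 10 without its replicate 2.

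Outside these lists, Igfbp4 (3.39), which encodes a binding protein of insulin-like growth factors, Dnai2 (3.06), Cfap206 (a cilium gene, 2.57), Stc2 (2.40), the epoxide hydrolase gene Ephx2 (613 ± 318 to 2684 ± 396, 2.22), Ifitm1 (2.12), Stk33 (2.07), the meiotic kinase gene Aurkc (2.03) and Serpina3m (1.90) rose. Rhox6 (-2.84), which has close copies, the BMP target Id1 (-2.31), Spry4 (-2.10), Rbfaos (-1.90) and Plaur (-1.85) fell, as did Gpnmb (-2.49), the transcription factor gene Gata2 (-2.44) and Krcc1 (-2.19) on chromosome 6.

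In all, 597 genes passed with limma, 260 higher and 337 lower in conv-dSVA_F&D, with no overlap of libraries in any of them. Of these, 215 differed at least 2-fold (125 higher, 90 lower). Chromosome 8 held 169 called genes, 168 of them lower, and chromosome 6 held 102, 97 of them lower (Fisher's exact test, adjusted p = 3.67e-78 and 7.49e-29). With chromosome medians set equal 196 genes passed, 142 higher and 54 lower, and without chromosomes 6, 8, 18 and Y 183 passed, 140 higher and 43 lower. The count was 1211 with DESeq2, 553 with edgeR, 200 with only the libraries of both sides, 0 with no variance trend (2535 at unadjusted p under 0.05) and 0 with no low-value filter (4058). It was 0 with limma without conv-dSVA_F replicate 1 (1794 at unadjusted p under 0.05, other tools not run) and 185 (103 higher, 82 lower) without its replicate 2, 181 and 176 without conv-dSVA_D replicates 1 and 2, and 881 without conv-dSVA_F&D replicate 1.

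Between conv-dSVA_F and conv-dSVA_D, each deleted for 1 of the SVA insertions, 5 of 14 2-cell-like and 4 of 11 trophoblast genes rose, and of 22 imprinted genes 6 rose and 1 fell (each list's adjusted p = 0.600 with an estimated correlation). H19 rose from 12.1 ± 3.25 normalized counts in conv-dSVA_D to 1327 ± 1093 in conv-dSVA_F (SD, n = 2; 6.39 ± 0.60, adjusted p = 0.00439). Krt8 rose from 80.1 ± 18.3 to 1187 ± 817 (3.70 ± 0.43, adjusted p = 0.0114) and the endocytic receptor gene Lrp2 from 369 ± 72.8 to 3707 ± 2258 (3.19 ± 0.34, adjusted p = 0.0109). Lefty2, a feedback inhibitor of Nodal, fell from 5215 ± 3819 to 906 ± 456 (-2.40 ± 0.46, adjusted p = 0.0408), and Tex13b fell from 558 ± 1.46 to 70.4 ± 7.59. The wild-type library also lay above both conv-dSVA_D libraries for H19 (350) and Krt8 (438), and below them for Tex13b. For these genes the outlying conv-dSVA_D level thus enters this comparison and the one with conv-dSVA_F&D. The conv-dSVA_F replicates also differed, with replicate 1 above replicate 2 for H19 (2100 and 554), Krt8 (1765 and 609) and Lrp2 (5304 and 2110).

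None of the 2-cell-like genes fell and 9 did not pass (11 rose when adjusted over the list alone; median 2.61, camera adjusted p = 5.55e-11; adjusted p = 0.600 with an estimated correlation). Zscan4d (3.46), Tmem92 (3.55), Zscan4a (3.33) and Zscan4c (2.97) led them. Of the 11 trophoblast genes 9 rose when adjusted over the list alone (median 3.15, camera adjusted p = 1.98e-08; adjusted p = 0.600 with an estimated correlation). The 4 past over all genes were Krt8, Krt18 (3.55) and the X-linked homeobox genes Rhox6 (3.53) and Rhox9 (3.30), which have close copies. For Rhox6 it was conv-dSVA_F that stood apart, at 1265 and 420 in replicates 1 and 2. Rhox6 stood at 73.0 and 53.1 in conv-dSVA_D, 51.3 and 199 in conv-dSVA_F&D and 162 in the wild type. Of 22 imprinted genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.61, camera adjusted p = 6.01e-05; adjusted p = 0.600 with an estimated correlation). H19, Peg3 (1057 ± 169 to 3105 ± 607, 1.55) and Peg10, a retrotransposon-derived gene on chromosome 6 (5.27 ± 0.88), rose, and Grb10 fell (-2.19). Peg10 replicates lay far apart, at 387 and 42.45 in conv-dSVA_D and 10105 and 2484 in conv-dSVA_F. Of 24 germline genes Hormad1 (0.98), Fkbp6 (1.58) and Stk31 (1.15) rose, and 4 did when adjusted over the list alone (median 0.63, camera adjusted p = 0.000613; adjusted p = 0.600 with an estimated correlation), with Ddx4 at 0.92.

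Of 19 naive pluripotency genes the AKT coactivator gene Tcl1 fell (-1.27 ± 0.22, adjusted p = 0.0288), and 4 fell when adjusted over the list alone (median -0.22, camera adjusted p = 0.00705; adjusted p = 0.670 with an estimated correlation). Esrrb (-0.51), Tfcp2l1 (-0.48) and Klf2 (-0.38) did not pass. Of 5 Y-linked genes Uty rose (1.85), and 3 did when adjusted over the list alone (median 1.04, camera adjusted p = 0.00255; adjusted p = 0.600 with an estimated correlation), with Ddx3y at 0.55, Eif2s3y at 2.14 and Kdm5d at 1.04.

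No member passed over all genes with limma in 4 lists that camera called. For 21 glycolysis and hypoxia genes (10 at unadjusted p under 0.05, 0 with edgeR, 4 with DESeq2) 6 fell when adjusted over the list alone (median -0.40, camera adjusted p = 1.17e-06; adjusted p = 0.688 with an estimated correlation), with Bnip3 at -1.32, Pgam1 at -0.48, Pgk1 at -0.89 and Eno1 at -0.63. For 18 TFIID subunits (6 at unadjusted p under 0.05, 0 with edgeR, 2 with DESeq2) 1 rose and 4 fell when adjusted over the list alone (median -0.19, camera adjusted p = 0.0114; adjusted p = 0.600 with an estimated correlation), with Taf5 at -0.70 (adjusted p = 0.0549), Taf6 at -0.54 and Taf15 at -0.78. For 20 genes of the G2 and M phases (3 at unadjusted p under 0.05, 0 with edgeR, 1 with DESeq2) none passed when adjusted over the list alone (median -0.14, camera adjusted p = 0.0180; adjusted p = 0.630 with an estimated correlation), with Nusap1 at -0.47, Bub1b at -0.39, Ube2c at 0.29 and Cenpf at -0.26. For 40 ribosomal protein genes (4 at unadjusted p under 0.05, 0 with edgeR, 1 with DESeq2) none passed when adjusted over the list alone (median 0.08, camera adjusted p = 0.0475; adjusted p = 0.835 with an estimated correlation), with Rpl13 at 0.55, Rps13 at 0.34, Rplp1 at 0.38 and Rpl12 at 0.28.

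Outside these lists, A2m, a protease inhibitor gene on chromosome 6 (-2.34), the noncoding RNA gene Tunar (-1.82), the inositol-trisphosphate kinase gene Itpka (1148 ± 2.80 to 347 ± 71.4, -1.74), Ephx2 (-1.55), Prelid2 (-1.46), Gpc3 (-1.42) and Tro (-1.41) fell. Among X-linked genes near Taf1 the amino acid transporter gene Slc7a3 fell (-0.94 ± 0.17, adjusted p = 0.0310). In all, 205 genes passed with limma, 165 higher and 40 lower in conv-dSVA_F, with no overlap of libraries in any of them, and 127 differed at least 2-fold (106 higher, 21 lower). Chromosomes 6 and 8 held 57 of the 165 higher genes (34.5%). Chromosome 6 held 42 called genes, 38 of them higher (Fisher's exact test, adjusted p = 1.35e-14). The count was 729 with DESeq2, 225 with edgeR, 504 with only the libraries of both sides, 126 without chromosomes 6, 8, 18 and Y, 1 with no variance trend and 0 with no low-value filter (3451 at unadjusted p under 0.05). It was 0 with limma without conv-dSVA_D replicate 2 (1839 at unadjusted p under 0.05, other tools not run), 3 without its replicate 1, 5 and 109 without conv-dSVA_F replicates 1 and 2, and 488 and 487 without conv-dSVA_F&D replicates 1 and 2.

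The test for any difference among the 3 converted groups called 850 genes with limma (3738 at unadjusted p under 0.05). It called 1887 with DESeq2, 835 with edgeR, 564 with chromosome medians set equal, 392 without chromosomes 6, 8, 18 and Y, 0 with no low-value filter (4408 at unadjusted p under 0.05) and 0 with no variance trend (2727). The count was 9 and 115 without conv-dSVA_D replicates 1 and 2, 40 and 354 without conv-dSVA_F replicates 1 and 2, and 1315 without conv-dSVA_F&D replicate 1.

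Between the converted groups and the wild-type library, which is 1 library assumed to vary like the converted groups, Taf1 and 4 of 14 2-cell-like genes fell and Spry4 rose (adjusted p = 0.819 with an estimated correlation for the 2-cell-like list). Spry4 stood at 49.1 normalized counts in the wild type and at 873 ± 583 (SD, n = 6) in the converted libraries (3.75 ± 0.48, adjusted p = 0.02). Zscan4a stood at 535 in the wild type and at 97.2 ± 74.3 (SD, n = 6) in the converted libraries (-3.10 ± 0.47, adjusted p = 0.0312). Sall1, a zinc-finger transcription factor gene on chromosome 8, rose from 297 to 838 ± 81.6 (1.49 ± 0.18, adjusted p = 0.0183). The fibroblast and feeder marker Thbs1 stood at 298 in the wild type and 12.4 ± 8.27 in the converted libraries (-4.71 ± 0.75, adjusted p = 0.0312).

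None of the 2-cell-like genes rose and 10 did not pass (12 fell when adjusted over the list alone; median -2.76, camera adjusted p = 5.22e-12; adjusted p = 0.819 with an estimated correlation). Zscan4a, Zscan4c (-2.77), Zscan4d (-2.71) and Tmem92 (-2.72) fell, as did the Eif1ad copies Eif1ad15 (1274 to 160 ± 106, -3.42), Eif1ad3 (-3.16), Eif1ad7 (-2.89) and Eif1ad8 (-2.35), a multicopy family in which reads may be shared. Of 40 ribosomal protein genes 4 fell and 1 rose (29 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 3.76e-17; adjusted p = 0.819 with an estimated correlation). Rps19 (-0.70), Rps27a (-0.77) and Rps23 (-0.66) fell and Rps16 rose (3641 to 9476 ± 1627, 1.36). The libraries also differed in abundant noncoding RNAs. The 7SK RNA took 5.10% of the reads in the wild type (Wilson 95% interval 5.09 to 5.11), 4.76% in conv-dSVA_F&D replicate 2 (4.75 to 4.77) and 3.41% to 4.05% in the 5 others (lowest and highest interval bounds 3.41 and 4.05). Rmrp took 3.44% (3.43 to 3.45), 3.09% (3.08 to 3.10) and 1.83% to 2.5% (1.83 and 2.5). Of 24 germline genes the ribosomal protein retrogene Rpl10l fell (-1.17), and 4 fell when adjusted over the list alone (median -0.61, camera adjusted p = 5.18e-05; adjusted p = 0.819 with an estimated correlation), with Hormad1 at -0.87, Stk31 at -1.04 and Dazl at -1.49.

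Of 16 ERK pathway feedback and target genes Spry4 rose, and 5 were higher and 1 lower when adjusted over the list alone (median 0.42, camera adjusted p = 0.0142; adjusted p = 0.819 with an estimated correlation). Etv4 (2.07, adjusted p = 0.0534), Spred1 (0.81, adjusted p = 0.0583) and Etv5 (-0.78, adjusted p = 0.0731) did not pass. Of 22 imprinted genes Mest (1.59), Nnat (2.32) and the long noncoding RNA gene Meg3 (1.75) rose, and 4 did when adjusted over the list alone (median 0.20, camera adjusted p = 0.0331; adjusted p = 0.819 with an estimated correlation), with Rian at 0.87. Of 9 fibroblast and feeder markers Thbs1 fell, and 3 fell when adjusted over the list alone (median -1.14, camera adjusted p = 0.0331; adjusted p = 0.819 with an estimated correlation). Acta2 stood at 299 in the wild type (-3.52, adjusted p = 0.0533), Col1a2 at 96.0 (-5.00, adjusted p = 0.105) and Fn1 differed by 0.38 (adjusted p = 0.267). Among TFIID subunits and X-linked genes near Taf1 only Taf1 passed. Of the 31 lists tested 6 were called, and 3 without chromosomes 6, 8, 18 and Y. Of 177 small noncoding RNAs 17 fell and 0 rose, with a median of -0.84. All annotated small noncoding RNAs, tested or not but without 7SK and Rmrp, took 1.39% of the reads in the wild type (Wilson 95% interval 1.386 to 1.396). Their share was 1.22% in conv-dSVA_F&D replicate 2 (1.211 to 1.222) and 0.692% to 0.845% in the 5 other converted libraries (lowest and highest interval bounds 0.689 and 0.849). The intervals cover counting error only. Without conv-dSVA_D replicates 1 and 2 the calls were 0 with limma (65 at unadjusted p under 0.05, other tools not run) and 5, without conv-dSVA_F replicate 2 5, and without conv-dSVA_F&D replicates 1 and 2 32 and 43, all lower.

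Outside these lists, Slc39a14 (119 to 954 ± 454, 2.82), Gprc5a (1.81) on chromosome 6, Wipf1 (1.63), Bmp2k (1.55) and the ribosomal RNA entry 5_8S_rRNA (1.69) rose, and the carbonyl reductase gene Cbr3 fell (-1.66). In all, 175 genes passed with limma, 95 higher and 80 lower in the converted groups, and 78 differed at least 2-fold (35 higher, 43 lower). With upper-quartile scaling the calls were 67 higher and 114 lower, and with edgeR and TMM 92 higher and 213 lower. Chromosomes 6 and 8 held 44 of the 95 higher genes (46.3%), 22 each (Fisher's exact test, adjusted p = 0.00017 for chromosome 6 and 0.00173 for chromosome 8). The count was 857 with DESeq2, 305 with edgeR, 275 with an added count of 5 and 906 (76 higher, 830 lower) with no low-value filter. It was 113 (43 higher, 70 lower) without chromosomes 6, 8, 18 and Y. No variance trend gave 1, and each side fitted as 1 group gave 0 (1603 at unadjusted p under 0.05). It was 2 (0 higher, 2 lower) and 16 (7 higher, 9 lower) without conv-dSVA_D replicates 1 and 2, 53 (21 higher, 32 lower) and 10 (2 higher, 8 lower) without conv-dSVA_F replicates 1 and 2, and 400 and 599 without conv-dSVA_F&D replicates 1 and 2.

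**Figure D4:**
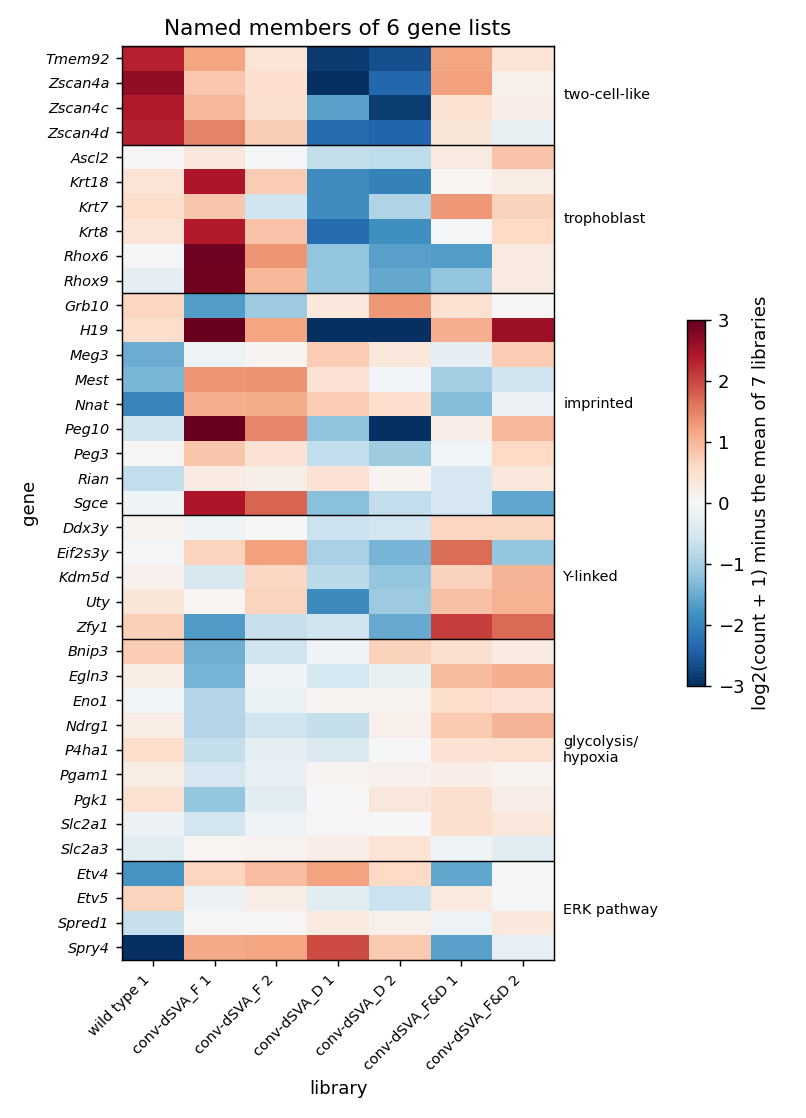
Log2 of the normalized count plus 1 in each of the 7 libraries, less the mean of the 7 libraries (color), for the named members of 6 gene lists. Zscan4a and Zscan4d are highest in the wild type and lowest in conv-dSVA_D, and H19 is lowest in both conv-dSVA_D libraries.

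Camera called none of 14 further lists in any of the 4 pairwise comparisons at the preset correlation: core pluripotency, formative and primed pluripotency, mesoderm, neuroectoderm, medium spiny neuron markers, p53 targets, interferon response, LIF and STAT3 targets, cholesterol synthesis, the unfolded protein response, heat shock, the mitochondrial genome, histones and DNA replication. Their lowest adjusted p was 0.0735 and their medians lay between -0.66 and 0.85.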

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

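The alternatives without chromosomes 6, 8, 18 and Y, with chromosome medians set equal and with protein-coding genes only were chosen after the data were seen, and the others before. Counts follow the order conv-dSVA_F&D with conv-dSVA_D (482 with the reported settings), conv-dSVA_F&D with conv-dSVA_F (597), conv-dSVA_F with conv-dSVA_D (205), converted with wild type (175) and any difference (850). With no low-value filter, which nearly doubled the genes adjusted together and lowered the prior degrees of freedom to 1.21, the counts were 0, 0, 0, 906 and 0 in limma (3823, 4058, 3451 and 4408 at unadjusted p under 0.05 for the counts of 0). With no variance trend they were 0, 0, 1, 1 and 0 (2452, 2535 and 2727 for the counts of 0). With only the libraries of both sides they were 246, 200, 504, 0 (1603, with the 6 converted libraries as 1 group) and 838. DESeq2 called 1041, 1211, 729, 857 and 1887 genes and shared 479, 586, 204 and 174 of the calls in the 4 pairwise comparisons. edgeR called 463, 553, 225, 305 and 835 and shared 449, 545, 203 and 167. An added count of 5 gave 275 for converted with wild type. Without chromosomes 6, 8, 18 and Y the counts were 350 (253 higher, 97 lower), 183, 126, 113 and 392. With chromosome medians set equal they were 502, 196, 209, 160 and 564. Leaving these chromosomes out also left fewer genes to test. Setting chromosome medians equal kept all 15240 genes and removed only the chromosome medians, so its lower counts follow from that removal. It does not remove shifts of part of a chromosome, as on chromosome 6 in conv-dSVA_D. Leaving out 1 converted library gave 0 to 769, 0 to 881, 0 to 488, 2 to 599 and 9 to 1315 genes. The counts of 0 had 1866 genes (without conv-dSVA_D replicate 1), 1794 (without conv-dSVA_F replicate 1) and 1839 (without conv-dSVA_D replicate 2) at unadjusted p under 0.05. The library left alone in its group was then assumed to vary like the other groups, and the cause was not tested.

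The Taf1 differences stayed at 1.5 and 1.02 with no low-value filter (adjusted p = 0.148 and 0.15) and no variance trend (0.142 and 0.191), neither past the threshold. The difference of -2.23 from the wild type missed it with no variance trend (0.176) and with only the libraries of both sides (0.329). Leaving out 1 library gave 1.4 to 1.6, 1.02 became 0.90 to 1.14, 0.48 became 0.36 to 0.60 and -2.23 became -2.27 to -2.19. Called lists numbered 13, 6, 10 and 6 in the pairwise comparisons, 0 in each with an estimated correlation and 3, 0, 0 and 0 with fry. Without chromosomes 6, 8, 18 and Y, 3 were called for converted with wild type. Leaving out 1 library gave 7 to 14, 2 to 10, 9 to 12 and 4 to 8 lists. Of the named genes and lists, Zfp42 and Rpl13 on chromosome 8 changed sign with chromosome medians set equal, to 0.13 and 0.15 for conv-dSVA_F&D over conv-dSVA_F, because that setting removes the chromosome's shift. All other named results kept their direction. Of 159 named genes and lists past the threshold, 107 were not without conv-dSVA_D replicate 1, and none of the 69 others newly passed. Without conv-dSVA_F&D replicate 1 these numbers were 27 and 21. With no low-value filter 124 of the 159 were lost, and with no variance trend all 124 genes.

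No paired analysis was possible because the labels carry no replicate numbers shared between groups. The other settings intended for the pre-conversion XDP library and for the striatal libraries were not run, since these samples were not analysed here. Depth limits low genes most in conv-dSVA_F&D replicate 2, where 3 reads correspond to 4.18 normalized counts.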

Other observations

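Of the tests below only the one on GC content and transcript length was written before its result was seen. The patterns were found in these data, so each explanation is a hypothesis.

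Chromosomes 6 and 8 were raised in conv-dSVA_F and chromosome 18 in conv-dSVA_F&D replicate 2. After a trend on GC content and transcript length was removed, the smallest of the 5 medians was 0.36, which argues against sequence bias. An extra copy of the whole chromosome may explain the shifts: every one of 6 parts was raised, the lowest by 0.25, against 0.58 for a ratio of 3 to 2 copies. In conv-dSVA_F replicates 1 and 2 the medians were 0.41 and 0.36 for chromosome 6 and 0.63 and 0.44 for chromosome 8. Most lay below 0.58, as did chromosome 18 (0.51), so the share of cells with an extra copy stays open. The partial shifts of conv-dSVA_D, on distal chromosome 6 and in replicate 2 on chromosome 8, were not tested for this. The labels give 1 line name per genotype, so a biological effect of the SVA deletions was not tested apart from changes acquired in culture.

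Taf1 was lower in the converted lines than in the wild-type library, and higher in conv-dSVA_F&D than in the single-deletion lines. Uncounted reads from the human-derived exons could contribute to the first difference. The highest converted level was 38.5% of the wild type, below the 65.7% of exon bases in exons 1 to 24, but the evenness of coverage is not known, so this cannot be told apart from lower expression. For the differences among the converted lines, the 20 X-linked neighbours had medians of at most 0.33 (SD 0.72) where Taf1 differed by 1.5. This argues against a shift of the same size across the neighbours only. A smaller or partial shift stays open. Against conv-dSVA_D, 15 of the 21 genes with Taf1 had positive differences, with Cited1 at 1.28 and Gjb1, not past, at 2.72. Camera called this list, which includes Taf1 itself, higher (adjusted p = 0.00432, and 0.397 with an estimated correlation). No list test was run without Taf1, so the call cannot say whether the neighbours shifted. An effect of the SVA deletions or of line differences on Taf1 stays open and untested.

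Of 14 genes of the 2-cell-like list, 6 were called lower in conv-dSVA_D than in conv-dSVA_F&D and 5 than in conv-dSVA_F (the list's adjusted p = 0.397 and 0.600 with an estimated correlation). A change confined to chromosome 7, where 8 of the 14 members lie, is argued against by a median of at least 2.59 over the 6 others. One scaling factor per library moves all genes alike. The list medians were at least 2.29 above the median of all genes (standard error 0.42). The pattern was picked because the list stood apart from the other genes, so this comparison is no separate test of scaling. A smaller share of cells in the 2-cell-like state is a candidate explanation that bulk values do not test, and a line difference unrelated to the SVA deletions stays equally open.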
